A study of Mus musculus with 5 samples.

How the data were processed

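RNA was measured in micro-punched caudate putamen of male C57BL/6 mice aged 9 weeks, as 5 sequencing libraries of total RNA. Per the labels' protocols, the tissue of 6 animals was pooled for each of the 4 stroke libraries, taken 4 hours, 1 day, 3 days and 10 days after photothrombosis. The sham library pooled punches of the opposite hemisphere; how many animals it holds, and from which times, is not given in the sources used here. RNA was extracted with Trizol and libraries were made with a total RNA kit, per the labels' protocols. Whether the counting used strand is not given in the sources used here, so reads of a gene and of a gene on the opposite strand cannot be told apart.

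The submitters' processing notes name Trimmomatic 0.36, HISAT2 2.1.0, StringTie 1.3.4d and the mouse build GRCm38, without their roles or order. The annotation version is not given in the sources used here. Per the file headers, the authors deposited 1 table of 19221 genes with 1 RPKM value (reads scaled by gene length and library total) per gene and library. The deposited table also holds a log2 fold and a GFOLD value at the setting 0.01 for each pair of libraries, per the file headers. GFOLD is a log2 fold shrunk towards 0 for genes with few reads, and its version is not given in the sources used here. The false discovery rate that the authors deposited with each pair is 1 for every gene. A p-value and an adjusted p-value per gene are deposited for 17959 genes and empty for 1262. The test behind them is not stated, so they were not used.

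Gene identifiers were matched to GENCODE mouse release 21 on GRCm38, which held 19158 of them (99.7%). Symbols and coordinates are those of that release, and 446 symbols differ from the ones in the table. The main value of each gene was its RPKM as deposited. Genes with at least 1 RPKM in at least 1 library were analysed, which left 12783, of which 10089 are protein coding. The fold of a gene was log2((stroke RPKM + 1) / (sham RPKM + 1)), a scale that understates the differences of low genes. A gene was counted as higher or lower by size where this log2 fold was at least 1 or at most -1, that is 2-fold with the pseudocount.

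With 1 library per group, no p-value, standard deviation or standard error was computed, and no test between conditions was made. For each of 61 gene lists of cell types, processes and library composition, the median log2 fold was set against 10000 random lists of the same size, matched in 20 bins of mean level. A list is said to stand apart where its percentile was at most 2.5 or at least 97.5 and at least 5 members were analysed, which 59 lists met. This describes these libraries. Lists share members, so the numbers of lists that stand apart are not numbers of separate findings. Lcn2 is in the neutrophil, pan-reactive astrocyte and iron lists, and Hmox1 in the hypoxia, oxidative stress and iron lists. Reactive astrocyte lists hold Cd14, also a monocyte and macrophage member, and H2-D1, also an antigen presentation member. By chance 5% of lists of unrelated genes would stand apart, and the rate for lists whose members vary together was not estimated.

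Depth was recovered from the steps in the low values. RPKM times the union exon length of the annotation gave whole reads, within 0.02 of a read, for 90.5% to 90.7% of the values below 5000 reads in each library. The read totals behind the RPKM values were 44924681 (sham), 45952916 (4 hours), 46323709 (day 1), 42261793 (day 3) and 48013846 (day 10). For a gene of 2 kb, 1 read was worth 0.0111 RPKM in the sham library. Even numbers made up 58.2% to 60.7% of the lowest read numbers, as where both mates of a pair are counted. Intervals of a ratio therefore use the reads divided by 2. They are exact conditional binomial intervals at 95% and cover counting error only, since reads copied in PCR are not independent molecules. They are given only for genes whose reads were whole in every library, or at least 5000.

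RPKM divides by all reads of a library, so a change in an abundant transcript moves the values of all other genes. Ribosomal RNA loci and the mitochondrial genome took shares of reads that differed between libraries, and the medians of all genes moved with the scaling. The counts were therefore also made with median-of-ratios scaling and with trimmed-mean-of-M-values scaling of the RPKM. The former used genes above 0 in all 5 libraries, and the latter set each library against sham, trimming 30% of M and 5% of A at each end without weights. They were also made without predicted, mitochondrial and small RNA genes, with the rest rescaled to the same total. Other alternatives were pseudocounts of 0.1 and 0.5, no filter, a floor of 5 RPKM, size limits of 1.5 and 2, and, for the time course, an 8-fold range. Alternatives chosen after seeing the data were a counting interval that must exclude 1, the 4-hour library as reference, the authors' deposited GFOLD value at the size limit, and median-of-ratios scaling of list medians between consecutive times.

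The thresholds, gene lists, other alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 8 genes with the largest positive and the 8 with the largest negative fold at each time, among genes with at least 5 RPKM in the higher library, leaving out predicted, mitochondrial, ribosomal and small RNA genes. It added up to 4 members of each list that stood apart, and the 4 genes of largest range among those highest in each library. Reads of near-identical copies (Hspa1a and Hspa1b, the alpha and the beta haemoglobin pairs) cannot be assigned with certainty. Of the named genes of largest fold, exons of Apoc2, Epo, Pcp4, Spp1 and Tcf20 overlap another gene on the same strand, and those of Cdr1, Cxcl10, Doc2b, Hspa1a, Ifi30, Tgm1 and Zfp36 a gene on the opposite strand.

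The procedure was tested on 2 simulated libraries with 200 changed genes, 40 at each size. True log2 folds of -2, -1.5, 1.5, 2 and 3 gave medians of -1.66, -1.37, 1.43, 1.95 and 2.93, and 6 of 11258 unchanged genes passed the size limit. Of 200 unchanged lists, 5.5% stood apart. The simulated libraries differed by counting error alone, and their unchanged lists were genes drawn at random. These rates therefore leave out differences between animals, punches and library preparations, and are not the rates for the 5 real libraries. A planted library factor of 1.5 was recovered as 1.51 by median-of-ratios and 1.50 by trimmed-mean scaling. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.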

Results

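Photothrombosis, in which laser light activates the dye rose bengal so that clots form in the lit vessels, was used to make a small ischaemic lesion inside the caudate putamen of mice. The dye was given at 100 mg/kg, and light of 532 nm and 30 mW was delivered for 2 min through an optical fibre 3 mm below the dura. Focal tissue was punched 4 hours, 1 day, 3 days and 10 days later and pooled from 6 animals into 1 RNA library per time. The control was 1 sham library pooled from the opposite side, which received the fibre and the laser before the dye. The design asks which transcripts differ from sham at each time and how they follow each other. Because each group is 1 library, none of the differences has a replicate check, and every value describes these libraries.

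The 5 libraries held between 42261793 and 48013846 reads. Loci carrying ribosomal RNA took 41.2% of the reads recovered on genes in the sham library, 26.5% at 4 hours, 34.4% at day 1, 28.8% at day 3 and 37.4% at day 10. The mitochondrial genome took 3.98%, 5.63%, 6.02%, 4.18% and 2.75% in the same order. The log2 factor that median-of-ratios scaling divides out, relative to sham, was 0.41 at 4 hours, -0.05 at day 1, 0.16 at day 3 and 0.14 at day 10, so scaled folds are lower where it is positive. List medians below are as deposited, and where the factor exceeded 0.1 the median after this scaling is given as well.

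**Figure D1:**
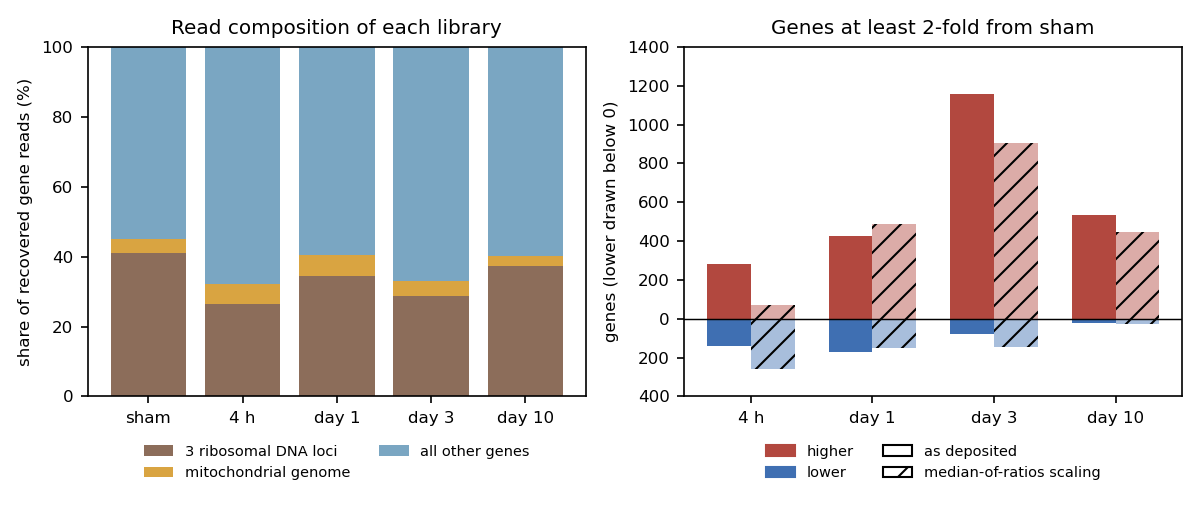
Left, share of recovered gene reads (%) taken by 3 ribosomal RNA loci, the mitochondrial genome and all other genes in each of the 5 libraries; right, number of genes at least 2-fold higher (above 0) or lower (below 0) than in sham at each time, as deposited (solid) and after median-of-ratios scaling (hatched). Ribosomal loci took 41.2% in sham and 26.5% at 4 hours, where 281 genes higher and 139 lower became 69 and 260, and day 3 had the most genes higher under both.

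At 4 hours, genes of the early response to injury were higher than in sham and genes of glial reactivity and interferon signalling were lower. Npas4, an activity-dependent transcription factor, was at 9.36 RPKM against 1.39 in sham (log2 fold 2.12). Fos was at 12.1 against 2.48 RPKM (1.91, ratio 4.88 with a counting interval of 4.04 to 5.94). Ccn1, which encodes a matricellular protein, was at 17.7 against 2.02 RPKM (2.63). In the other direction Timp1, an inhibitor of metalloproteinases, was at 0.368 against 11.1 RPKM (log2 fold -3.15, ratio 0.033 with a counting interval of 0.0136 to 0.0676).

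Of 20 measured immediate early genes, 9 were at least 2-fold higher at 4 hours and 0 were 2-fold lower, with a list median of 0.62 at percentile 99.9 of matched random lists (0.23 after median-of-ratios scaling). Among them Atf3 had a log2 fold of 1.72 and Fosb of 1.52. Other leading genes were Hspa1a, an inducible heat shock protein (1.85), Zfp36, which promotes mRNA decay (1.79), and the glucocorticoid-induced Tsc22d3 (1.78). The axon regeneration list (median 0.77, scaled 0.52) was led by Atf3 and Jun (1.24). The hypoxia list (0.53, scaled 0.21) was led by Ddit4 (1.22) and Bnip3 (1.07). The unfolded protein response list (0.56, scaled 0.20) was led by Ppp1r15a (1.08) and Herpud1 (1.06).

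Myelin genes stood apart on the high side at 4 hours, with 4 of 14 at least 2-fold higher and a median of 0.80 (scaled 0.40). Mog was at 105 against 33.2 RPKM, and Mal and Cldn11 had log2 folds of 1.55 and 1.52. Cholesterol synthesis genes had a median of 0.69 (scaled 0.37), with Msmo1 at 1.36 and Insig1, a sterol-regulated gene, at 1.10. Ependymal and choroid plexus markers had a median of 0.88 (scaled 0.67). Ttr, the transthyretin gene of choroid plexus, was at 729 against 77.4 RPKM (3.22), and Folr1 and Kcnj13 at 1.67 and 1.45. Cortical excitatory neuron markers had a median of 0.59 (scaled 0.24), with Nrn1 at 1.60. Medium spiny neuron markers, which define the projection neurons of the striatum, did not stand apart at this time, and the sign of their median turned with the scaling (0.31, percentile 60.3, scaled -0.10).

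The pan-reactive astrocyte list had the lowest median at 4 hours, -1.26 (scaled -1.61), below all 10000 random lists, with 5 of 10 genes at least 2-fold lower. Gfap, the intermediate filament of astrocytes, was at 26.3 against 102 RPKM (-1.91), Serpina3n at 4.66 against 33.0 (-2.59) and Lcn2 at 0.780 against 10.3 (-2.66). Interferon response genes had a median of -0.95 (scaled -1.14), with 6 of 14 lower, including Isg15 (-2.45), Bst2 (-1.95) and Irf7 (-1.80). Antigen presentation genes had a median of -0.69 (scaled -0.92), with H2-K1 at -1.73 and H2-D1 at -1.71. The general astrocyte and homeostatic microglia lists did not stand apart, and their signs turned with the scaling (0.26 and 0.09, scaled -0.13 and -0.11). Chemokines went both ways, with Ccl12 at -2.87 and Cxcl10, which overlaps a gene on the opposite strand, at -2.68, while Ccl3 was at 9.74 against 3.37 RPKM. Cdr1, likewise with a gene on the opposite strand, was at -2.30.

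In all, 281 genes were at least 2-fold higher and 139 lower at 4 hours (189 and 43 protein coding). The larger side turned after median-of-ratios scaling, with 69 higher and 260 lower. Of the 59 lists with enough members, 11 stood apart high and 17 low. General neuron, presynaptic and glycolysis lists stood apart high as deposited (0.56, 0.50 and 0.46) and no longer did so after this scaling (0.16, 0.10 and 0.06).

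At day 1, chemokine and neutrophil genes were higher than in sham, while striatal projection neuron and homeostatic microglia markers were lower. Ccl3 was at 69.1 against 3.37 RPKM (log2 fold 4.00, ratio 20.5 with a counting interval of 15.8 to 27.2). S100a9, an alarmin of neutrophils and monocytes, was at 93.4 against 5.50 RPKM (3.86, ratio 17.0, interval 13.2 to 22.2). Drd1, the dopamine receptor gene of direct-pathway projection neurons, was at 2.68 against 7.60 RPKM (-1.22). Tmem119, a marker of resident microglia, was at 3.98 against 14.0 RPKM (-1.59, ratio 0.284, interval 0.243 to 0.332).

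Of 15 measured chemokines, 10 were at least 2-fold higher at day 1 and the list median was 2.87, above all random lists. Ccl4 had a log2 fold of 3.76, Ccl2 of 3.60 and Cxcl2 of 3.29, and Ccl12 reached 206 RPKM. Of 6 measured neutrophil genes (of 16 listed), 5 were higher, with S100a8 at 3.26. Inflammatory cytokine genes had a median of 1.23 with 10 of 12 higher, among them Il1rn (2.44), Il1b (1.94) and Socs3 (1.87). Monocyte and macrophage genes had a median of 0.81, led by Cd14 at 2.67.

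Stress genes were also higher at day 1. Hspa1a, whose reads cannot be told from those of Hspa1b, was at 38.3 against 2.18 RPKM (3.63), and Hspb1 at 54.6 against 9.11 (2.46). The heat shock list had 5 of 14 genes higher and a median of 0.43. Hmox1, which degrades haem, was at 226 against 31.8 RPKM (2.79) and led the oxidative stress list (median 0.81). The coagulation and fibrinolysis list had a median of 1.13, with Anxa2 at 2.23. Sprr1a, a gene of regenerating axons, was at 23.3 against 0.911 RPKM (3.67), and Atf3 was at 3.15. The immediate early list had a median of 0.49, with Fos at 1.59. Ribosomal protein genes had a median of 0.75.

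Reactive astrocyte lists differed in their medians at day 1. All 7 measured genes of the list named A2 were at least 2-fold higher (median 1.85), including Tm4sf1 (2.82) and Tgm1 (2.70). The pan-reactive list had 7 of 10 higher (median 1.26), with Timp1 at 2.34, and the list named A1 did not stand apart (-0.04). General astrocyte markers had a median of -0.44, with the glutamate transporter gene Slc1a2 at -0.86. Oligodendrocyte precursor markers had a median of -0.47, with Gpr17 at -1.20.

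Medium spiny neuron markers had a median of -0.87 at day 1, below all random lists, with 7 of 17 at least 2-fold lower. Pde10a was at -1.22, and Ppp1r1b, the gene of the phosphoprotein DARPP-32, was at 476 against 1019 RPKM (-1.10). Presynaptic genes had a median of -0.30, with the vesicular GABA transporter gene Slc32a1 at -1.12. Voltage-gated channel, glutamate receptor and GABA receptor lists had medians of -0.54, -0.45 and -0.42. Striatal interneuron markers did not stand apart (0.04). Cortical excitatory markers were on the high side (0.33, percentile 98.9), with Slc17a7 at 86.6 against 59.1 RPKM, and Ttr was at 303 RPKM (1.95).

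Homeostatic microglia markers had a median of -0.55 at day 1 with 2 of 12 at least 2-fold lower. They were Selplg (-1.67) and Tmem119, and the purinergic receptor gene P2ry12 was at 0.170 against 0.857 RPKM (-0.67). Crybb1, a microglial gene outside the list, was at 1.05 against 9.29 RPKM (-2.33). Among the other low genes, Lingo3 was at -1.38, and Epo (-1.42) and Tcf20 (-1.36) overlap exons of other genes. In all, 426 genes were at least 2-fold higher and 172 lower at day 1 (304 and 57 protein coding), with 22 lists apart high and 11 low. After median-of-ratios scaling 489 were higher and 150 lower.

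At day 3, genes of phagocytes, lysosomes and dividing cells were higher than in sham, and haemoglobin genes and several neuronal lists were lower. Lgals3, the galectin-3 gene of activated phagocytes, was at 198 against 2.37 RPKM (log2 fold 5.88, ratio 83.3 with a counting interval of 68.4 to 103). Plin2, which coats lipid droplets, was at 77.4 against 2.31 RPKM (4.57), and Spp1, the osteopontin gene, at 62.2 against 1.97 (4.41). Cdc20, which drives mitotic exit, was at 10.8 against 0.655 RPKM (2.83). Cyfip2, a regulator of actin in neurons, was at 11.6 against 27.8 RPKM (-1.20, ratio 0.416, interval 0.393 to 0.440).

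The phagocytosis and lysosome list had 14 of 17 genes at least 2-fold higher at day 3 and a median of 1.86 (scaled 1.71). Cd68 was at 211 against 12.8 RPKM (3.94) and the cathepsin gene Ctsd at 1631 against 169 (3.27). Disease-associated microglia genes had a median of 2.04 (scaled 1.88), with 11 of 17 higher, and complement genes of 1.74 (scaled 1.60), with C1qa at 780 against 108 RPKM. Homeostatic microglia markers had 8 of 12 higher and a median of 1.38 (scaled 1.24), including Fcrls (3.27) and Tmem119 (1.71). Monocyte and macrophage genes had 8 of 11 higher (median 1.74, scaled 1.59), with Arg1 at 10.2 against 0.160 RPKM (3.27). Neutrophil genes did not stand apart (0.10, scaled 0.02). Lgals1 (4.88), Capg (4.44), Ifi30 (4.12) and S100a11 (4.04) were among the genes of largest fold.

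Of 15 measured cell cycle genes, 13 were at least 2-fold higher at day 3, with a median of 1.75 (scaled 1.63). Plk1 had a log2 fold of 2.78, Cdk1 of 2.50 and Ccnb2 of 2.31, and the replication-dependent histone list, led by Hist1h2ab (2.46), had a median of 0.86 (scaled 0.70). Pan-reactive astrocyte genes had a median of 1.61 (scaled 1.49), with Gfap at 509 RPKM (2.31) and Vim at 107 against 5.90 (3.97). The A1 and A2 lists had medians of 1.41 and 1.38 (scaled 1.27 and 1.24). Iron-handling genes Hmox1 and Ftl1, a ferritin light chain gene, were at 3.39 and 2.82.

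Antigen presentation genes had a median of 1.47 (scaled 1.34) and interferon response genes of 0.74 (scaled 0.63), led by Ifi27l2a (3.85). Chemokines had a median of 0.72 (scaled 0.58) with 7 of 15 at least 2-fold higher, and the leading members were Ccl8 (2.66), Cxcl16 (2.61) and Ccl6 (2.18). Coagulation and fibrinolysis genes had a median of 1.64 (scaled 1.51), with the urokinase gene Plau at 2.64.

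Medium spiny neuron markers had a median of -0.61 at day 3 (scaled -0.76) with 2 of 17 at least 2-fold lower, and striatal interneuron markers did not stand apart (-0.03, scaled -0.15). Presynaptic genes had a median of -0.52 (scaled -0.63), with Gad1, which makes GABA, at -0.94. Voltage-gated channel genes had a median of -0.61 (scaled -0.71). Lmtk2 (-1.19) and Doc2b (-1.17), which overlaps a gene on the opposite strand, were among the lowest genes. Astrocyte markers had a median of -0.31 (scaled -0.47), with Slc1a2 at -0.98. Cortical excitatory markers were at -0.25 (scaled -0.32) and cholesterol synthesis genes at -0.24 (scaled -0.32). Haemoglobin genes had a median of -1.37 (scaled -1.53), with 4 of 6 lower, and Hbb-bt was at 224 against 728 RPKM (-1.70).

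Day 3 had the most genes beyond the size limit of the 4 times, with 1156 higher and 79 lower (871 and 41 protein coding) and 26 lists apart high and 13 low. After median-of-ratios scaling 908 were higher and 147 lower.

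At day 10, genes of antigen presentation, lipid handling and phagocytes were higher than in sham, and few genes were lower. Cst7, a cystatin gene of activated microglia, was at 52.9 against 1.06 RPKM (log2 fold 4.71, ratio 49.9 with a counting interval of 33.2 to 78.5). Lyz2, the macrophage lysozyme gene, was at 245 against 10.7 RPKM (4.39, ratio 22.8, interval 20.4 to 25.6). Cd74, the invariant chain of class II molecules, was at 43.1 against 4.20 RPKM (3.08). Apoe, which carries lipids between cells, was at 4442 against 952 RPKM (2.22).

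Of 12 measured antigen presentation genes, 11 were at least 2-fold higher at day 10, with a median of 2.50 (scaled 2.37). The class II genes H2-Aa and H2-Ab1 had log2 folds of 3.35 and 3.30. Disease-associated microglia genes had 15 of 17 higher (median 2.14, scaled 2.03), with Gpnmb at 25.1 against 0.677 RPKM (3.96). Phagocytosis and lysosome genes had 15 of 17 higher (1.77, scaled 1.64), complement genes 9 of 12 (1.85, scaled 1.72) and homeostatic microglia genes 9 of 12 (1.44, scaled 1.32). The lipid efflux list had a median of 0.87 (scaled 0.75), led by Trem2 at 73.2 against 6.52 RPKM (3.30). Apoc2 and Apoc1 were at 3.78 and 3.73, and Saa3, an acute-phase gene, was at 27.3 against 0.376 RPKM (4.36). Inflammasome pathway genes had a median of 1.84 (scaled 1.72), with Pycard at 2.23, and interferon response genes of 0.95 (scaled 0.85).

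Extracellular matrix genes had a median of 1.02 at day 10 (scaled 0.89) and meningeal fibroblast markers of 0.88 (scaled 0.81). Col1a1 was at 3.38 against 0.343 RPKM (1.71) and Col3a1 at 2.24 against 0.0930 (1.57). T and NK cell genes had a median of 0.69 (scaled 0.60), with 2 of 8 at least 2-fold higher and low levels throughout, such as Nkg7 at 2.39 against 0.268 RPKM (1.42). Ccl5, a chemokine made by T and NK cells among others, was at 11.3 against 0.441 RPKM (3.09). Cell cycle genes did not stand apart (0.24, scaled 0.19).

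Neuronal lists stood apart on the low side at day 10 with 0 members beyond 2-fold. Medium spiny neuron markers had a median of -0.24 (scaled -0.35), presynaptic genes of -0.20 (scaled -0.33) and striatal interneuron markers of -0.22 (scaled -0.30). Mitochondrially encoded genes had a median of -0.51 (scaled -0.64), with mt-Co3 at 3303 against 6268 RPKM (-0.92). Cholesterol synthesis genes had a median of -0.32 (scaled -0.40). Hmox1 was at 16.8 against 31.8 RPKM (-0.88), and Pcp4, whose exons overlap those of Igsf5, at -0.71.

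In all, 537 genes were at least 2-fold higher and 22 lower at day 10 (434 and 3 protein coding), with 21 lists apart high and 13 low. The 3 protein coding genes were Ttr at 0.205 RPKM (-6.02), Ccl7 (-1.46) and Tekt4 (-1.07), the last named after its values were seen. After median-of-ratios scaling 445 genes were higher and 28 lower.

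**Figure D2:**
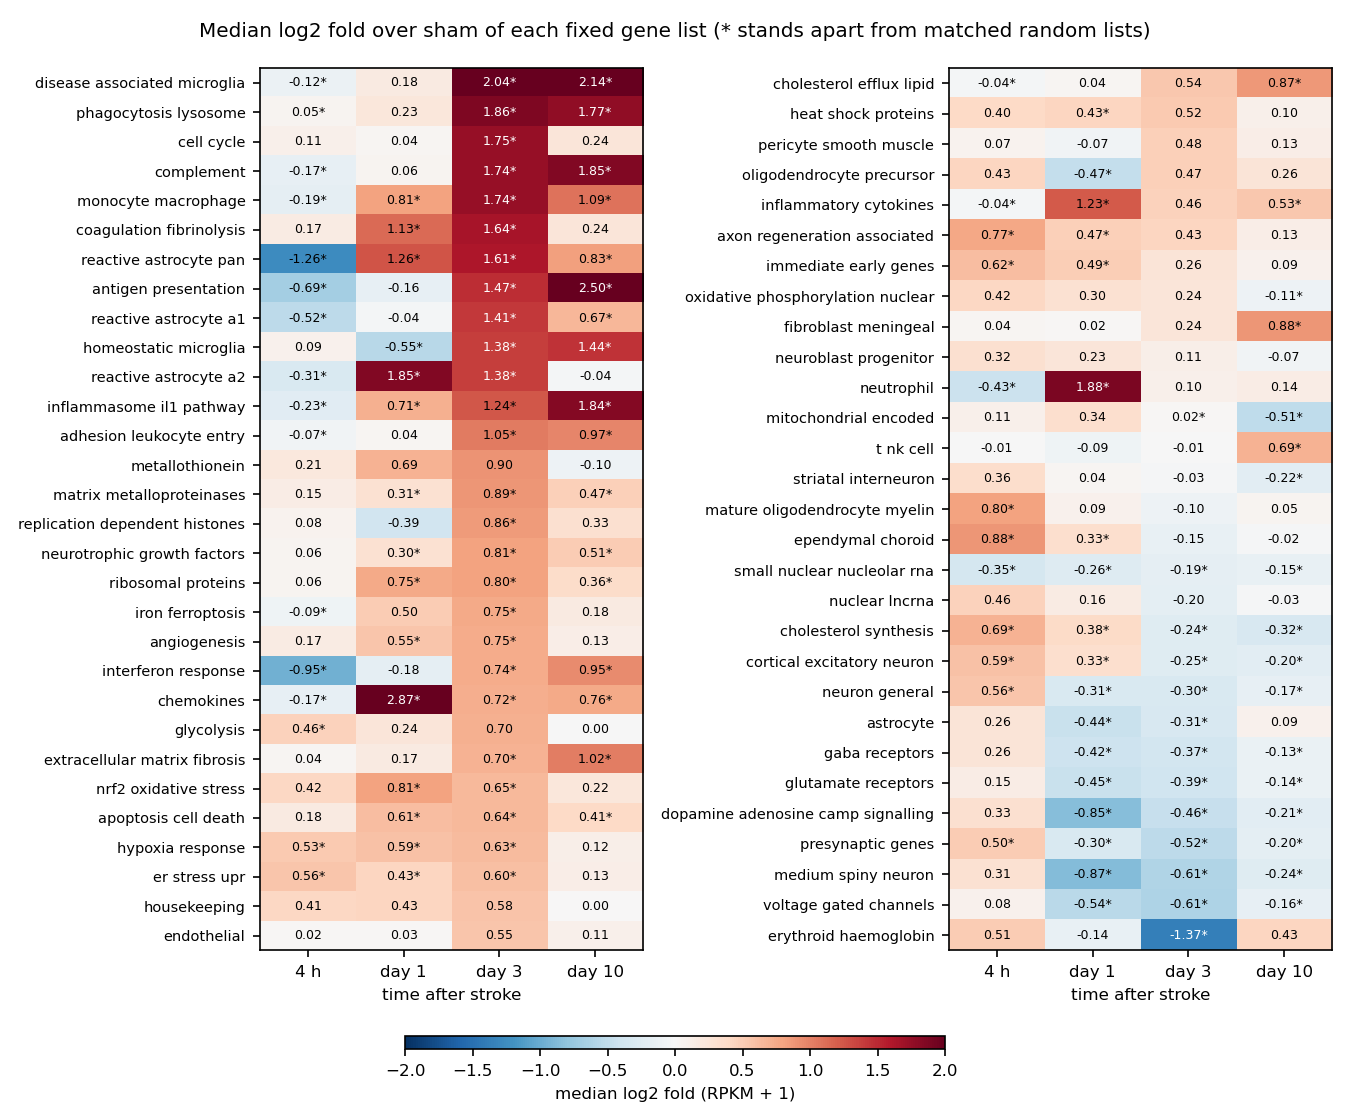
Median log2 fold over sham (RPKM + 1, as deposited) of each gene list with at least 5 analysed genes, with 1 row per list and 1 column per time, with an asterisk where the list stood apart from matched random lists. The chemokine list is at 2.87 at day 1, disease-associated microglia at 2.04 and 2.14 at days 3 and 10, and medium spiny neurons at -0.87, -0.61 and -0.24 at days 1, 3 and 10.

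Compared with one another, the stroke libraries differed in immune, glial, cell cycle and haemoglobin genes among others. Over 484 genes whose highest library was at least 4-fold above the lowest, day 3 was the highest library for 260, day 10 for 129, day 1 for 54, 4 hours for 31 and sham for 10. The lowest library was 4 hours for 268 of them, day 1 for 103 and sham for 76. Among genes highest at 4 hours, Arrdc2 was at 11.9 RPKM against 1.35 at day 3. Cnr1, a cannabinoid receptor gene of neurons, was highest in sham with a range under 4-fold, at 6.86 RPKM against 2.22 at day 1.

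From 4 hours to day 1 the neutrophil list had a median log2 fold of 2.97 (scaled 3.16), the pan-reactive astrocyte list of 2.72 (2.99) and the chemokine list of 2.45 (2.60), and medium spiny neuron markers of -1.08 (-0.65). From day 1 to day 3 neutrophil genes were at -2.06 (scaled -2.12) and chemokines at -1.09 (-1.19), while homeostatic microglia genes were at 1.97 (1.79) and cell cycle genes at 1.76 (1.62). From day 3 to day 10 cell cycle genes were at -1.64 (scaled -1.57) and the A2 list at -1.24 (-1.17), with T and NK cell genes at 0.71 (0.72) and haemoglobin genes at 1.69 (1.68). Each of these lists stood apart from matched random lists, as deposited and scaled. Scaling divides a library by 1 factor, which moves list and random lists alike except through the pseudocount. The kept calls are therefore little further evidence.

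Day 1 had 345 genes at least 2-fold higher and 728 lower than 4 hours, which became 838 and 128 after median-of-ratios scaling. Day 3 had 953 higher and 120 lower than day 1 (671 and 186 scaled). Day 10 had 80 higher and 354 lower than day 3 (81 and 330 scaled). Across the 12783 genes, which are not independent replicates, the Spearman correlation of levels was highest between sham and 4 hours (0.957) and between days 3 and 10 (0.951). It was lowest between 4 hours and day 3 (0.859). Over genes with at least 5 RPKM in every library the highest pair was sham and day 10 (0.963).

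**Figure D3:**
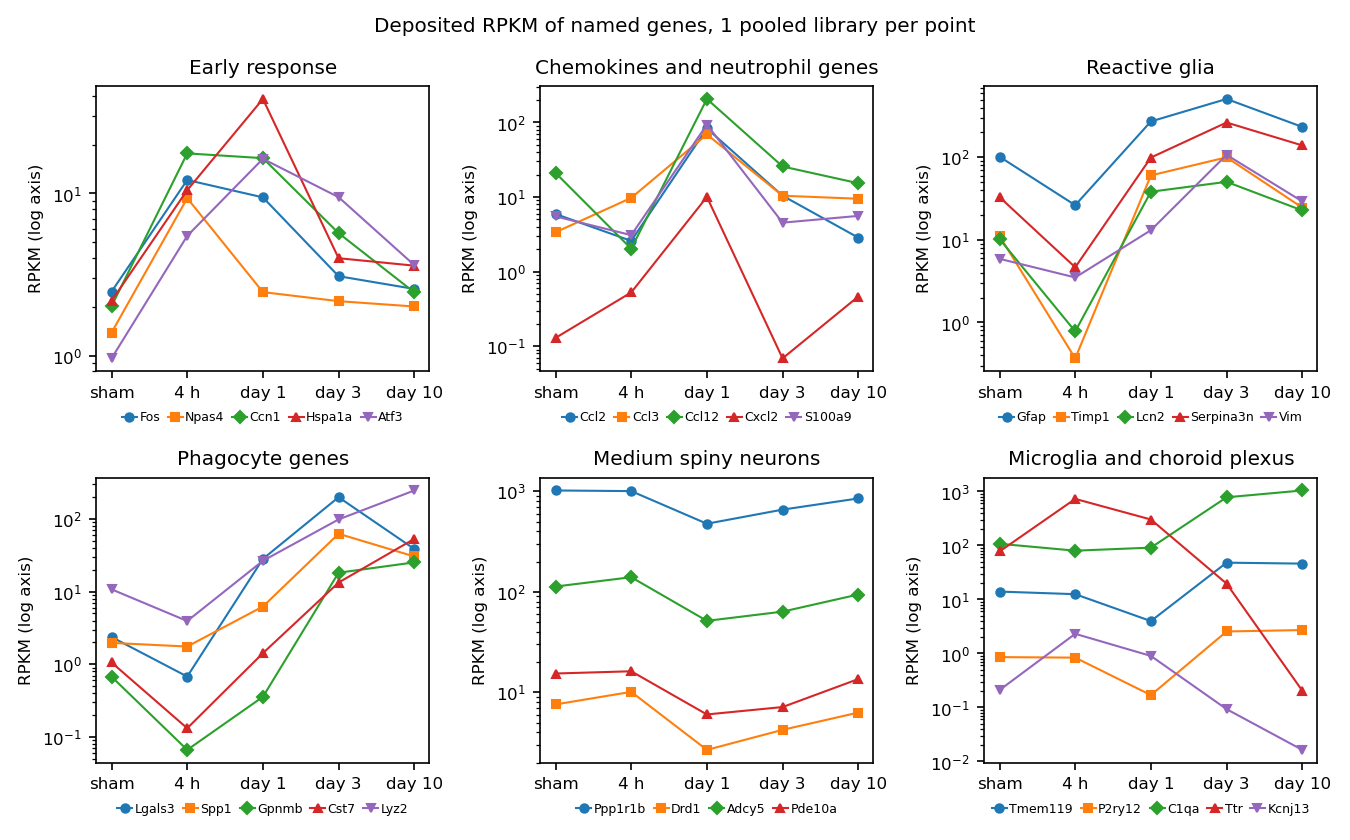
Deposited RPKM (log axis) of named genes in the sham library and at 4 hours, 1, 3 and 10 days, with 1 pooled library per point and lines that only join the points of a gene. The chemokine and neutrophil genes drawn are highest at day 1 (Ccl12 at 206 RPKM), Lgals3 at day 3 (198 RPKM) and Lyz2 at day 10 (245 RPKM), and the choroid plexus genes Ttr and Kcnj13 at 4 hours (729 and 2.31 RPKM).

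Some of the named genes lie at these GRCm38 positions in GENCODE release 21. Lgals3 (ENSMUSG00000050335) lies on chromosome 14 from 47367751 to 47386160 on the plus strand, and Cst7 (ENSMUSG00000068129) on chromosome 2 from 150570415 to 150578944 on the plus strand. Ccl3 (ENSMUSG00000000982) lies on chromosome 11 from 83647844 to 83649355 on the minus strand, and its neighbour Ccl4 (ENSMUSG00000018930) from 83662584 to 83664683 on the plus strand. Timp1 (ENSMUSG00000001131) lies on chromosome X from 20870166 to 20874735 on the plus strand. Ttr (ENSMUSG00000061808) lies on chromosome 18 from 20665280 to 20674321 on the plus strand. All values are totals over the annotated exons of a gene.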

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

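All tests in this part were chosen after the result they bear on was seen, except the test of gene length and GC content, and none of the differences between times listed here was tested.

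Several genes were at least 2-fold above sham at one time and at least 2-fold below it at another. The log2 fold over sham of Lgals3 differed by 6.89 between day 3 and 4 hours, that of Timp1 by 6.21, Serpina3n by 5.55, Lcn2 by 4.85, Bst2 by 4.79 and Isg15 by 3.78. Ccl12 differed by 6.10 between day 1 and 4 hours, and Lyz2 by 5.64 between day 10 and 4 hours. The median of the pan-reactive astrocyte list differed by 2.88 between day 3 and 4 hours. Ttr differed by 9.24 between 4 hours and day 10. The microglial genes Crybb1 (3.73, day 10 against day 1), Selplg (3.56, day 3 against day 1) and Tmem119 (3.30, day 3 against day 1) lay below sham at day 1 and above it later.

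The first pattern is that 43 genes, leaving out predicted, mitochondrial and small RNA genes, were at least 2-fold lower at 4 hours than in sham (median -1.59). Among them were genes of glial reactivity, interferon signalling and antigen presentation. Scaling of the 4-hour library is argued against as the cause by the sign of its median-of-ratios factor relative to sham (0.41 on the log2 scale). Dividing by this factor lowers every 4-hour fold, so the scaled median of -1.66 was bound to be low and adds no further evidence. Less glial RNA in the 4-hour punches is argued against as the only cause by the astrocyte and homeostatic microglia medians of 0.29 and 0.09. The former leaves out genes of the pattern. Scaled, the medians of the whole lists were -0.13 and -0.11. The pattern's genes were picked for low folds at 4 hours, so their distance from these lists is no evidence. Of the lists fixed beforehand, the pan-reactive astrocyte list was at -1.26 at 4 hours, and the whole astrocyte list at 0.26. The microglia list was at percentile 4.7 of matched lists. Monocyte and macrophage, complement, disease-associated microglia and phagocytosis lists stood apart low, so a part by less RNA of microglia or macrophages stays open. It also stays open that the sham tissue may carry transcripts of the later response, for example after insertion of the fibre. The same genes had a median of 1.42 over sham at day 3, at percentile 100 of matched lists. Of the 43 genes, 34 were above sham then, although they were picked for high sham values. These values cannot tell high sham levels from a decrease in the stroke tissue at 4 hours, since either could come before a rise by day 3. Such a decrease was not tested, and times and number of the sham animals are not given in the sources used here.

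The second pattern is that Ttr was at 77.4 RPKM in sham, 729 at 4 hours, 303 at day 1, 19.6 at day 3 and 0.205 at day 10. A change of Ttr alone is argued against by the other choroid plexus markers, whose median log2 ratio of 4 hours over sham was 2.63 with a pseudocount of 0.01. Choroid plexus tissue in some punches may be the source, since 5 of the 5 other markers (Folr1, Kl, Otx2, Kcnj13 and Clic6, the last named after its values were seen) were highest at 4 hours. At the other times the markers did not all follow Ttr. Folr1 (1.16 against 0.717 RPKM in sham) and Kcnj13 (0.901 against 0.210) did so, above sham at day 1 and falling at days 3 and 10. At day 1 Clic6 (0.287 against 0.739 RPKM in sham), Kl and Otx2 were below sham, and Clic6 and Kl were higher at day 10 than at day 3. Kl and Otx2 rest on few reads (19 and 0 at day 1). The markers as a set thus leave the Ttr values after 4 hours unexplained.

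The third pattern is that medium spiny neuron markers were lower at day 1 (median -0.87). Dilution by RNA of cells without interneuron or myelin transcripts is argued against as the only cause. The median lay -0.91 from that of interneuron markers (bootstrap interval over genes -1.49 to -0.38) and -0.96 from that of myelin genes (-1.41 to -0.61). These intervals leave out differences between punches, with 1 library per group. Added tissue that itself carries interneuron and myelin transcripts could hold those lists up, so dilution by such tissue is not addressed. Astrocyte (-0.44), oligodendrocyte precursor (-0.47), homeostatic microglia (-0.55) and general neuron (-0.31) lists also stood apart low, so a part by dilution stays open. A trend with gene length and GC content is argued against by a median of -0.74 after its removal. A punch with more cortex may contribute, as the cortical excitatory list was at 0.33 (percentile 98.8), and this stays open. The cortical list was also high at 4 hours (0.59, scaled 0.24), where the medium spiny list did not stand apart (0.31, scaled -0.10), and at day 3 it was at -0.25.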

How the results depend on the processing

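The alternatives chosen after seeing the data were the counting interval, the 4-hour reference, the GFOLD limit and the scaling of list medians between consecutive times. Genes are given as higher and lower than sham, and values are listed where a count moved by more than 1.5 times or a correlation changed rank. The cause was not tested unless stated. With a pseudocount of 0.1, which lets low genes pass by construction, counts were 835 and 377 at 4 hours, 771 and 604 at day 1, 1780 and 321 at day 3, and 1034 and 71 at day 10. With 0.5 they were 456 higher at 4 hours, and 314 lower at day 1 and 146 at day 3. A floor of 5 RPKM, with fewer genes, left 354 and 9 at day 10. Median-of-ratios scaling gave 69 and 260 at 4 hours and 147 lower at day 3, and trimmed-mean scaling 68, 262 and 168. Without predicted, mitochondrial and small RNA genes there were 41 and 70 at 4 hours, 232 and 92 at day 1, 599 and 156 at day 3, and 5 lower at day 10. A size limit of 1.5, stricter by construction, gave 45 and 65, 121 and 32, 476 and 15, and 239 and 11 at the 4 times, and a limit of 2 gave 16 and 22, 54 and 8, 228 and 1, and 109 and 7. With the 4-hour library as reference, 728 genes were lower at day 1, 885 at day 3 and 456 at day 10. At day 10 the counting interval left 13 genes lower and the authors' deposited GFOLD value 10. Lists apart high at 4 hours numbered 7 in place of 11 both with a pseudocount of 0.1 and without the small RNA and predicted genes. Genes highest in sham, 4 hours, day 1, day 3 and day 10 numbered 38, 128, 129, 606 and 357 with a pseudocount of 0.1 and 2, 9, 22, 92 and 56 with an 8-fold range, and median-of-ratios scaling left 14 highest at 4 hours. Over the 4354 genes with at least 5 RPKM in every library, sham correlated with 4 hours at 0.939, day 1 at 0.914, day 3 at 0.901 and day 10 at 0.963, 4 hours with day 1 at 0.898, and day 1 with days 3 and 10 at 0.927 and 0.912. Of 1704 list values under alternatives, 1582 kept their call, 75 no longer stood apart, 39 newly did and 8, of lists that stood apart as deposited, changed sign. The floor of 5 RPKM accounted for 37 of the 75 that no longer stood apart, and not all of these are named here. Under this floor, lists left with fewer than 5 members could not stand apart, whatever their medians. Those 8 were the phagocytosis list at 4 hours (-0.18 median-of-ratios, -0.19 trimmed mean, -0.15 without small RNA and predicted genes), mitochondrially encoded genes at day 3 (-0.13 median-of-ratios, -0.17 trimmed mean), growth factors at day 10 (-0.0197 with a floor of 5 RPKM), adhesion genes at 4 hours (0.000255 without a filter) and small nuclear RNA at day 10 (0.003425 without predicted genes). Median-of-ratios and trimmed-mean scaling move list members and matched random lists alike, except through the pseudocount. Most list calls were therefore bound to be kept under them. Of 448 values of the genes named for the largest folds at each time, 445 stayed the same, 3 moved and 0 reversed. These genes were picked for lying far from 0, so their stability says nothing about genes near the size limit. Another expression unit was not run, since the table holds RPKM only. Leaving out a replicate is not possible with 1 library per group, for which reason that was not run. No paired analysis was possible because each group is 1 library.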

Other observations

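No test of an explanation is made in this part, and the genes and lists described were picked after the results were seen. Genes of cell death and growth factors showed their own time courses, in values not given above. The cell death list stood apart high at days 1, 3 and 10 (medians 0.61, 0.64 and 0.41, scaled by median-of-ratios 0.65, 0.56 and 0.33), with the death receptor gene Tnfrsf1a at 1.43, 1.78 and 1.11 and Bax at 48.3 against 19.9 RPKM at day 3. Cdkn1a, a cell cycle inhibitor, was higher at 4 hours (1.25), day 1 (1.18) and day 3 (1.00) and at -0.35 at day 10. The growth factor list stood apart high at the same 3 times (0.30, 0.81 and 0.51, scaled 0.33, 0.74 and 0.45). With a floor of 5 RPKM it did so at none of them, and its day 10 median was -0.0197. A list left with fewer than 5 members by that floor could not stand apart, whatever its median. Gdf15, a stress-induced cytokine gene, was at 0.264 RPKM in sham, 4.90 at day 1, 1.47 at day 3 and 4.58 at day 10. The metalloproteinase list was at 0.31, 0.89 and 0.47 (scaled 0.34, 0.80 and 0.41), and Mmp3 was at 5.95 RPKM at day 1, 1.22 at day 3 and 4.78 at day 10 against 0.247 in sham.

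Angiogenesis genes stood apart high at days 1 and 3 (0.55 and 0.75, scaled 0.59 and 0.61), led by Angptl4 (1.07) and Pgf (1.03) at day 1, while endothelial and pericyte lists did not stand apart at any of the 4 times over sham. The adhesion list was at 1.05 and 0.97 at days 3 and 10 (scaled 0.94 and 0.87), with the integrin gene Itgb2 at 2.49 and 2.15 and Icam1 at 1.06 and 1.37. With a floor of 5 RPKM the cell death, metalloproteinase, angiogenesis and adhesion lists no longer stood apart at these times either. Here too a call may have been lost through the number of members left, so this does not show smaller medians. Metallothionein genes did not stand apart (0.69 at day 1 and 0.90 at day 3, both 0.74 scaled).

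Small RNA genes made up most of the 22 genes lower at day 10. The predicted microRNA gene Gm24187, named after its values were seen, was at 4366 RPKM in sham and at 29.4, 32.2, 46.1 and 166 RPKM at 4 hours, 1, 3 and 10 days. The Y RNA gene Rny1 was at 324 RPKM in sham and 152 at 4 hours.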
